A study of Mus musculus with 12 samples.

How the data were processed

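Striatal RNA from 12 pools of 4 mice was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per pool. The values used are those the authors deposited as a table of 28815 rows, on a log scale taken here as log2. The deposited values are centred: in each row the saline arrays 1 and 2, 3 and 4, and 5 and 6 sum to 0 within 1e-06. Background correction, normalization and summarisation are not given in the sources used here. The log base is not stated either. Of the 28801 rows with enough decimals to read the rounding, 76.2% hold multiples of a step that single-precision numbers have between 4 and 8, and 23.8% a step they have between 8 and 16, which is the range of log2 array values. Direction was taken as deposited, so a positive value is above the baseline. Which saline arrays form the baseline of each morphine or butyrate-morphine array stays unknown. No platform probe build is named, so coordinates are not printed.

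Probe sets were named from the platform annotation table. Of the rows, 21780 had exactly 1 gene symbol and were tested, 1605 had several symbols and 5430 had none. Of those tested, 21689 had an Entrez ID in the RefSeq table of assembly GRCm38.p6, used for names only, and 0 symbols changed. The tested probe sets covered 19936 genes, 997 of them with more than 1 probe set.

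Groups were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on all 12 arrays with 3 group means and 1 shared spread. Benjamini-Hochberg adjustment ran over all tested probe sets, with a threshold of 0.05. The fit had 9 residual and 3.87 prior degrees of freedom, and the median residual SD was 0.0743. The contrasts were each morphine group against saline, butyrate-morphine against morphine, and the mean of both morphine groups against saline. Gene lists (22 lists, 310 members, 283 measured) were tested with camera at a preset correlation of 0.01, with the estimated correlation and with fry. In the list tests each gene was the mean of its probe sets, and list calls were adjusted over 19936 genes. The adjusted p of a gene named in the general part of a comparison was adjusted over probe sets, as were those of single genes in fits without an array.

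The groups, the alternatives, the tests, the lists and the rule for named genes were fixed before the data were examined. The rule takes, among probe sets past the threshold whose arrays do not overlap between groups, the 12 largest rises and the 12 largest falls, passing over unnamed and predicted genes and olfactory or vomeronasal receptors. Where fewer than 5 qualify it takes the 10 lowest p-values. From each list it takes up to 6 members past the threshold in any comparison, or else the 2 with the lowest p. Further list members given in the text were chosen after their values were seen. The rule's choice of the brightest probe set could not be applied to centred values, whose rounding shows only a coarse class: the highest mean of the deposited values was used for the leading genes and the mean of probe sets for list members.

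The procedure was tested on simulated arrays with the real spread per probe set, each set of arrays centred on the mean of 1 pair of saline arrays. In 10 runs over 21780 probe sets of morphine against saline, 71.2% of genes changed 1.2-fold, 99.6% of those changed 1.5-fold and 100% of those changed 2-fold were recovered. False calls made up 7.99% of calls, above the nominal share, and 5.68% of unchanged probe sets had p under 0.05. For butyrate-morphine against morphine, with 400 changed probe sets per run, 65.9% of 1.2-fold changes were recovered. So many true changes loosen the adjusted threshold, so recovery is lower where few genes differ. A simulated 25% larger response with butyrate passed fry in 5 of 5 runs, and with no difference 0 of 5 runs passed. Camera found a shifted list in 10 of 10 runs, with 1 false call among 210 unshifted lists. Fry also found it in 10 of 10 runs, with 4 false calls among 210. Genes varied independently in these runs, so the rates do not cover correlated lists.

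Alternatives were quantile normalization, median centring, all rows, eBayes with trend and robust, array weights, only the groups compared, the replicate number as a block, only saline arrays 1 to 3 or 4 to 6, other thresholds and each array left out. The planned filters on mean brightness could not be run, since centred values keep only the coarse class that rounding shows. Added after seeing the data were a test against the baseline at 0, mirror pairs counted once, 1 value per gene, and only probe sets whose rounding step shows stored values of 8 or more.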

Results

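Gene expression was measured in the striatum of male Swiss-Albino mice, a forebrain region that receives dense dopamine input and expresses opioid receptors. The animals were 2 months old. The series asks whether sodium butyrate, an inhibitor of histone deacetylases, enlarges the response to repeated morphine. Per the labels, mice received 6 induction injections on alternate days, with morphine at 20 mg/kg preceded by saline or by butyrate at 300 mg/kg, or saline throughout. A challenge injection followed 7 days later, and RNA was taken 1 h after it. The RNA of 4 animals was pooled for each Affymetrix Mouse Gene 1.0 ST array. There were 6 saline arrays, 3 morphine arrays and 3 butyrate-morphine arrays. The labels disagree on the saline group's challenge: the source names give saline, while the protocol text gives morphine to all animals. A difference from saline therefore holds either the acute and the repeated morphine injections together, or the repeated ones alone.

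The deposited values are log2 differences from a baseline, and saline arrays 1 and 2, 3 and 4, and 5 and 6 sum to 0 in every row. The saline mean is thus 0 for every gene, and the 6 saline arrays hold 3 independent values per gene. A fit without 1 saline array keeps its mirror image and the baseline that array helped form. Such a fit moves the saline mean off 0 and does not show the data without that pool. Centring removed the level of each probe set, apart from a coarse class read from rounding (stored values of 4 to 8 or of 8 to 16), and the number of arrays limits the precision. Array medians over the 21780 probe sets with a single gene name lay between -0.0153 and 0.0136. Values below are log2 differences from the saline mean, with the SD over the 3 arrays of the group. Whether the pools of a group came from separate cohorts is not given in the sources used here, so p-values measure the spread between pools.

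The first comparison, morphine against saline, asks which genes differed after repeated morphine without butyrate. The largest rise was in Ttr, the thyroid hormone carrier made by the choroid plexus, at 13.4-fold (3.75 ± 0.08, SD, n = 3, adjusted p = 8.84e-07). Kcnj13, an inwardly rectifying potassium channel gene, rose 5.96-fold (2.58 ± 0.31, adjusted p = 4.33e-07). Lbp, which encodes the lipopolysaccharide-binding protein, rose 3.19-fold (1.67 ± 0.05, adjusted p = 3.74e-07). Sgk1, the serum- and glucocorticoid-regulated kinase gene, rose 2.09-fold (1.06 ± 0.07, adjusted p = 4.33e-07). Kdr, the main endothelial receptor for vascular endothelial growth factor, fell to 0.644 of the saline level (-0.64 ± 0.04, adjusted p = 2.51e-06).

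Other leading rises were in Polr3e, an RNA polymerase III subunit (2.46-fold), Sostdc1, a secreted inhibitor of growth factor signalling (2.23-fold), and Kl, the co-receptor Klotho (2.2-fold). They continued with the folate receptor gene Folr1 (1.95-fold), calretinin (Calb2, 1.92-fold) and the zinc finger transcription factor Zbtb16 (1.9-fold). The nuclear receptor Nr4a1 rose 1.86-fold and the glucose transporter Slc2a12 rose 1.83-fold. Calb2 varied most among these, with an SD of 0.56, and is also a marker of neighbouring thalamus and septum. Nr4a1 was no longer called without morphine array 1 or morphine array 3, with an adjusted p of up to 0.067.

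Besides Kdr, leading falls were in the Ras exchange factor Rasgef1b (0.668 of saline), the blood-brain barrier tight junction gene Cldn5 (0.674) and Trim59 (0.683). P2ry13, an ADP receptor of microglia, fell to 0.697, and the iron exporter ferroportin (Slc40a1) fell to 0.713 with an adjusted p of 2.28e-05. Smaller falls were in Cdc42ep1 (0.728), Gask1b (0.731), the unconventional myosin Myo3b (0.735) and the potassium channel subunit Kcnv1 (0.736). Cwc22, a splicing factor, had the largest of the named falls, at 0.596 of saline with an SD of 0.42, and the Wnt enhancer Rspo2 was at 0.723. Of the 12 fits that left out an array, Cwc22 passed in 3, those without morphine array 1 or butyrate-morphine array 1 or 3 (adjusted p up to 0.132). Rspo2 passed in 4, those without morphine array 1 or any butyrate-morphine array (up to 0.143). Cldn5 missed the threshold without morphine array 3 (adjusted p = 0.0557).

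Glucocorticoid-responsive genes rose together. Of 26 measured, 16 rose and 0 fell, with a median of 0.35, and 22 rose when adjusted over the list alone. Leaving out 1 array at a time gave 12 to 16 rises. Pdk4, a brake on pyruvate oxidation, rose by 0.80 ± 0.06 and the inhibitor of NF-kappaB Nfkbia by 0.64 ± 0.11. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 0.52 ± 0.07, and Tsc22d3 (GILZ), a steroid-induced leucine zipper gene, rose by 0.48 ± 0.15. The list differed from the other genes with adjusted p = 1.96e-31 by camera, and adjusted p = 0.00109 with an estimated correlation. Beside these rises, the choroid plexus markers were higher in the same arrays.

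All 9 measured choroid plexus markers rose, with a median of 0.96, and 9 rose when adjusted over the list alone. Beyond Ttr, Kcnj13 and Kl, the chloride channel gene Clic6 rose by 0.83 and the homeobox gene Otx2 by 0.79. Camera gave adjusted p = 8.05e-32, and adjusted p = 0.0015 with an estimated correlation. The mean over these markers was 1.40, 1.46 and 1.23 in the 3 morphine arrays, against -0.114 to 0.114 in the saline arrays. Igf2, counted here among meningeal markers and also made by the choroid plexus, rose by 0.85 ± 0.10. It was the 1 riser of 8 meningeal genes measured, with 3 when adjusted over the list alone, and 2 rose without saline array 5 or morphine array 1. The meningeal list had camera adjusted p = 5.69e-05, lost at adjusted p = 0.103 with an estimated correlation.

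Endothelial markers moved down. Of 9 measured, 4 fell (Kdr, Cldn5, Tek and Flt1), and 7 fell when adjusted over the list alone. Tek, the angiopoietin receptor, fell by 0.38, while the transporters Slco1c1 (-0.04) and Abcb1a (-0.08) did not pass. Camera gave adjusted p = 6.99e-10, and adjusted p = 0.00612 with an estimated correlation. Of 9 microglia markers, the fractalkine receptor Cx3cr1 fell by 0.30 and the integrin Itgam by 0.21, with 4 falls when adjusted over the list alone (camera adjusted p = 0.000101, and adjusted p = 0.0847 with an estimated correlation). Cx3cr1 missed the threshold without morphine array 3 (adjusted p = 0.0544), and Itgam passed only without saline array 2 or 3 or morphine array 1 (up to 0.143).

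Immediate early genes, which neurons switch on within minutes of activity, were mixed. Of 26 measured, 7 rose and 0 fell, and adjusted over the list alone 8 rose and 4 fell. The phosphatase gene Dusp1 rose by 0.76 ± 0.09, the activity-dependent factor Npas4 by 0.66 ± 0.17, Fos by 0.57 ± 0.10 and the synaptic gene Arc by 0.61 ± 0.29. Egr1 was at -0.03 ± 0.23 and Nr4a2 at -0.40 ± 0.43, and neither passed. The list's median was 0.0871, with camera adjusted p = 5.69e-05 and adjusted p = 0.31 with an estimated correlation. Without morphine array 3 the rises numbered 3, with Fos at adjusted p = 0.0587. Without morphine array 1, 4 rose and 4 fell. Nr4a3 (0.35) passed only without morphine array 2 or butyrate-morphine array 1 or 3 (adjusted p up to 0.18).

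Dopamine signalling genes and indirect-pathway markers tended to be lower, by small amounts, and so did direct-pathway markers. The direct-pathway median was -0.161, beside -0.159 for indirect-pathway markers, with 2 of 8 direct-pathway markers above saline. Camera did not call the direct-pathway list (adjusted p = 0.0572), while fry did (adjusted p = 0.00963). Of 12 dopamine signalling genes, 5 fell, and 9 fell when adjusted over the list alone. The cannabinoid receptor Cnr1 was at -0.31 ± 0.16, the phosphodiesterase Pde10a at -0.17 ± 0.06, the adenylyl cyclase Adcy5 at -0.16 ± 0.06, the G protein Gnal at -0.19 ± 0.07 and the dopamine receptor Drd2 at -0.16 ± 0.03. Without morphine array 3 the list held 0 calls. It held 3, 1, 2, 2, 3 and 2 without saline arrays 1 to 6 in turn. Camera gave adjusted p = 9.09e-07, and adjusted p = 0.0847 with an estimated correlation. Of 5 indirect-pathway markers, Drd2 and Gpr52 (-0.28) passed, and 4 fell when adjusted over the list alone (camera adjusted p = 5.69e-05, and adjusted p = 0.0847 with an estimated correlation). Gpr52 passed only without saline array 1 (adjusted p up to 0.137), and Drd2 only without morphine array 1 or butyrate-morphine array 2 or 3 (up to 0.118).

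Some markers of tissue next to the striatum differed in the morphine arrays, unevenly between arrays. Of 8 thalamic and septal markers, Calb2, the vesicular glutamate transporter Slc17a6 (0.81 ± 0.44) and the channel Trpc4 (0.49 ± 0.19) rose, and 4 rose when adjusted over the list alone. Their mean was 0.09 in morphine array 1, 0.54 in array 2 and 0.65 in array 3 (camera adjusted p = 7.29e-05, and adjusted p = 0.173 with an estimated correlation). Without morphine array 3, 1 of these markers passed, with Trpc4 at adjusted p = 0.0907. Slc17a6 passed only without morphine array 1 or butyrate-morphine array 1 or 2 (adjusted p up to 0.161). None of 6 cortical excitatory neuron markers passed, and 1 fell when adjusted over the list alone. Without morphine array 1, 4 of them fell. Their mean was 0.14 in morphine array 1, -0.68 in array 2 and -0.31 in array 3 (camera adjusted p = 0.0341, and adjusted p = 0.35 with an estimated correlation).

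In the lists that camera did not call, single genes passed. Rgs4, a regulator of G protein signalling, fell by 0.20 among 12 opioid system genes, whose receptors Oprm1 (-0.04), Oprd1 (-0.13) and Oprk1 (-0.06) did not pass. Adjusted over the list alone, 2 opioid system genes rose and 3 fell. Gabrb1 (0.21) and Grik1 (0.33) rose among 28 glutamate and GABA receptor genes, Ndufb9 fell by 0.22 among 26 oxidative phosphorylation genes, and the connexin Gjb6 rose by 0.41 among 9 astrocyte markers. Per1 rose by 0.32 and Arntl fell by 0.24 among 15 clock genes, though Arntl missed the threshold when adjusted over probe sets (adjusted p = 0.0524). Without morphine array 3, Per1 (adjusted p = 0.0989) and Gabrb1 (0.0773) missed it. Rgs4 missed it without saline arrays 2, 4 or 6 or morphine arrays 2 or 3 (up to 0.1), and Grik1 passed only without saline array 3, morphine array 1 or butyrate-morphine arrays 1 or 2 (up to 0.157). Without morphine array 1, 4 receptor genes rose and 2 fell, and 1 opioid system gene rose. Calls over all genes were 0 of 12 heat shock, 0 of 24 histone acetylation, 0 of 12 interferon-responsive, 0 of 8 direct-pathway, 0 of 8 interneuron and 0 of 10 oligodendrocyte genes. Of these, histone acetylation gave 1 call without saline array 3, 2 without morphine array 2 and 1 without morphine array 1, which also gave 2 for interneurons, and oligodendrocytes gave 1 without saline array 6. The blood list was represented by Alas2 alone, at 0.02. Adjusted over the list alone, the direct-pathway list had 1 rise and 5 falls, histone acetylation 1 and 1, interneurons 0 and 1, receptors 5 and 2, oxidative phosphorylation 0 and 2, astrocytes 2 and 0, and clock genes 1 and 2. The heat shock, interferon-responsive, oligodendrocyte and blood lists had 0 on that basis.

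Over all probe sets, limma called 534 at adjusted p under 0.05, with 284 higher and 250 lower. At least 2-fold changes were seen for 7, all of them higher. An unadjusted p under 0.05 was seen for 3360 probe sets, where the nominal rate gives 1089. The count was 219 without morphine array 3. Without morphine array 1 it was 1092, with the balance turned to 435 higher and 657 lower. It was 323, 287, 343 and 314 without saline arrays 1, 2, 3 and 4, whose mirror images stayed in the fit. Quantile normalization left 69 calls, split 56 higher and 13 lower. It was applied to centred values, whose SD over probe sets was 0.052 to 0.0845 in saline and 0.112 to 0.151 in other arrays. Forcing these to 1 distribution widens the saline spread and narrows the responses, so this count does not test ordinary normalization. Counting each mirror pair of saline arrays once, an alternative chosen after seeing the data, left 310. Testing only probe sets with stored values of 8 or more, also chosen then, gave 65 higher and 143 lower.

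**Figure D1:**
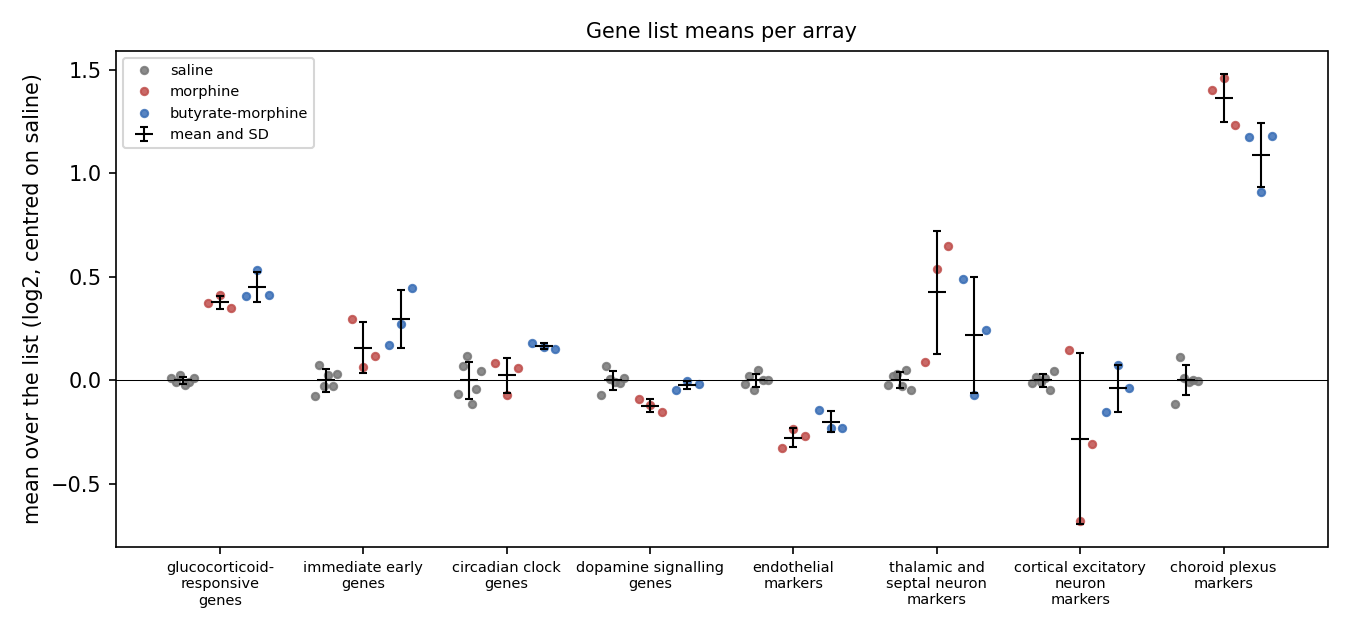
Mean of each gene list per array (y axis, log2 centred on saline) for 8 lists (x axis), with a point per array, the group mean as a dash and the SD as bars. Choroid plexus markers sit at 1.40, 1.46 and 1.23 in the morphine arrays, and the glucocorticoid-responsive list lies above the saline arrays in both treated groups.

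The second comparison, butyrate-morphine against saline, asks the same of mice that received butyrate during induction. Ttr again led, at 10.7-fold (3.42 ± 0.23, SD, n = 3, adjusted p = 4.77e-06), with Kcnj13 at 4.2-fold. Nr4a1 rose 2.41-fold (1.27 ± 0.45, adjusted p = 0.00271) and Zbtb16 rose 2.26-fold (1.17 ± 0.15, adjusted p = 4.77e-06). Dusp1, which switches off mitogen-activated kinases, rose 2.17-fold (1.12 ± 0.19, adjusted p = 4.77e-06), and Npas4 rose 1.97-fold (0.98 ± 0.10, adjusted p = 0.000122). Cldn5 fell to 0.598 (-0.74 ± 0.09, adjusted p = 0.00118) and Kdr to 0.664 of saline (-0.59 ± 0.07, adjusted p = 4.77e-06).

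The other leading rises were Polr3e (2.61-fold), Lbp (2.33-fold), Sgk1 (2.07-fold), Kl (1.92-fold), Pdk4 (1.87-fold) and the adiponectin receptor Adipor2 (1.76-fold). Falls were seen in Rasgef1b (0.704 of saline), the argonaute Ago4 (0.722), P2ry13 (0.733) and Magef1 (0.758). Slc40a1 (0.76), the clock repressor Cry1 (0.761), the interferon-inducible GTPase Gbp4 (0.765) and Cdc42ep2 (0.767) fell as well. The endoplasmic reticulum gene Sdf2l1 was at 0.702 and Pate11 at 0.729 of saline. Sdf2l1 was lost without butyrate-morphine array 1 or 2 (adjusted p up to 0.0786), and Pate11 without saline arrays 1, 4 or 5 or butyrate-morphine arrays 1 or 2 (up to 0.14).

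Of 26 glucocorticoid-responsive genes, 23 rose and 0 fell, with a median of 0.43. Adjusted over the list alone, 23 rose and 1 fell. Without butyrate-morphine array 2, 15 rose. Nfkbia rose by 0.74 ± 0.07, Fkbp5 by 0.61 ± 0.19, the sulfotransferase Sult1a1 by 0.54 ± 0.04 and the metallothionein Mt2 by 0.39 ± 0.02. Camera gave adjusted p = 3e-33, and adjusted p = 0.000843 with an estimated correlation. Of 9 choroid plexus markers, 8 rose in the same arrays (median 0.75, 9 when adjusted over the list alone, and 7 to 9 with 1 array left out), with camera adjusted p = 2.62e-22 and adjusted p = 0.00582 with an estimated correlation.

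Of 26 immediate early genes, 9 rose and 0 fell, and 13 rose when adjusted over the list alone. Fos rose by 0.81 ± 0.35, Arc by 0.73 ± 0.26, Fosb by 0.39 ± 0.17 and Btg2, an antiproliferative gene, by 0.40 ± 0.23. Egr1 was at 0.13 ± 0.18 and did not pass. The median was 0.17, with camera adjusted p = 6e-09 and adjusted p = 0.198 with an estimated correlation.

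Clock genes split by direction. Of 15 measured, 4 rose (Per1, Ciart, Nr1d1 and Per3) and 2 fell (Cry1 and Arntl), and adjusted over the list alone 6 rose and 2 fell. Per1, a clock gene also induced by glucocorticoids, rose by 0.64 ± 0.06, and the nuclear receptor Nr1d1 (Rev-erb alpha) rose by 0.41. Arntl (Bmal1), which peaks in the opposite phase, fell by 0.35. Camera gave adjusted p = 0.00276, and adjusted p = 0.349 with an estimated correlation. Nr1d1 missed the threshold without butyrate-morphine array 2 (adjusted p = 0.0521), and Per3 passed only without saline array 3 or 6 or any morphine array (up to 0.125). The rises numbered 2 without saline arrays 1 or 5 or any butyrate-morphine array.

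Of 9 endothelial markers, 4 fell (Cldn5, Kdr, Tek and Flt1), with 4 when adjusted over the list alone (camera adjusted p = 5.8e-05, and adjusted p = 0.0634 with an estimated correlation). Flt1 was lost without butyrate-morphine array 2 or 3 (adjusted p up to 0.0626), and Tek without these or saline arrays 1 or 4 (up to 0.108), with 2 falls left in the list without butyrate-morphine array 3. Of 9 microglia markers, Cx3cr1 fell by 0.32, with 3 falls when adjusted over the list alone (camera adjusted p = 0.00167, and adjusted p = 0.185 with an estimated correlation). Of 8 meningeal markers, Igf2 (0.62) and Aebp1 (0.18) rose, with 3 when adjusted over the list alone (camera adjusted p = 0.00276, and adjusted p = 0.234 with an estimated correlation). Of 26 oxidative phosphorylation genes, the subunits Ndufb9 (-0.15) and Sdhb (-0.23) fell, and 6 fell when adjusted over the list alone. That list had camera adjusted p = 0.00182 and adjusted p = 0.171 with an estimated correlation. Ndufb9 missed the threshold when adjusted over probe sets (adjusted p = 0.0505). Sdhb passed only without saline array 6 or any morphine array (up to 0.145), and Aebp1 missed without saline arrays 1 or 4 or butyrate-morphine arrays 2 or 3 (up to 0.109). The oxidative phosphorylation list held 5 falls without morphine array 3, and 0 or 1 without any 1 of the saline or butyrate-morphine arrays.

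None of 12 dopamine signalling genes, 5 indirect-pathway markers, 8 thalamic and septal markers or 6 cortical markers passed in this comparison. Leaving out morphine array 3 gave 1 call each in the dopamine and thalamic lists, and leaving out saline array 1 gave 1 in the indirect-pathway list. The indirect-pathway list had camera adjusted p = 0.00849, and adjusted p = 0.234 with an estimated correlation. Among lists that camera did not call, Rgs4 fell by 0.21, Gabrd, a GABA receptor subunit, fell by 0.28, and the direct-pathway marker Sfxn1 (0.28) and Gjb6 (0.31) rose. Gabrd missed the threshold when adjusted over probe sets (adjusted p = 0.0516). Sfxn1 (adjusted p up to 0.107) and Gjb6 (up to 0.143) passed in 5 of the 12 fits without an array, each losing the call without any 1 of the butyrate-morphine arrays. Sfxn1 also lost it without saline arrays 1, 2, 5 or 6, and Gjb6 without 1, 2, 4 or 6. Rgs4 lost it without saline arrays 2, 4 or 6 or any butyrate-morphine array (up to 0.129). Without morphine array 3, 2 receptor genes rose and 1 direct-pathway marker fell. Without morphine array 1, 1 receptor gene and 2 astrocyte markers rose, and 2 astrocyte markers rose without saline array 5. Heat shock, histone acetylation, interferon-responsive, interneuron and oligodendrocyte lists held 0 calls, though histone acetylation gave 1 without morphine array 2 and interferon-responsive genes gave 1 without morphine arrays 1 or 2. Alas2 of the blood list was at 0.18. Adjusted over the list alone, astrocytes had 3 rises and 1 fall, opioid system genes 1 and 1, direct-pathway markers 1 and 1, receptors 0 and 1 and indirect-pathway markers 0 and 1. Histone acetylation, interferon-responsive and blood lists each had 1 rise, and the dopamine, thalamic, cortical, heat shock, interneuron and oligodendrocyte lists had 0.

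Over all probe sets, limma called 512, with 383 higher and 129 lower, and 8 changed at least 2-fold, all higher. The count was 206 and 232 without butyrate-morphine arrays 1 and 2, and 284 and 287 without saline arrays 1 and 4. It was 807 without morphine array 2, which enters through the shared spread. An unadjusted p under 0.05 was seen for 3752. Quantile normalization, with the same limit as above, left 95 calls, and counting each mirror pair once left 314. Testing only probe sets with stored values of 8 or more gave 109 higher and 69 lower.

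**Figure D2:**
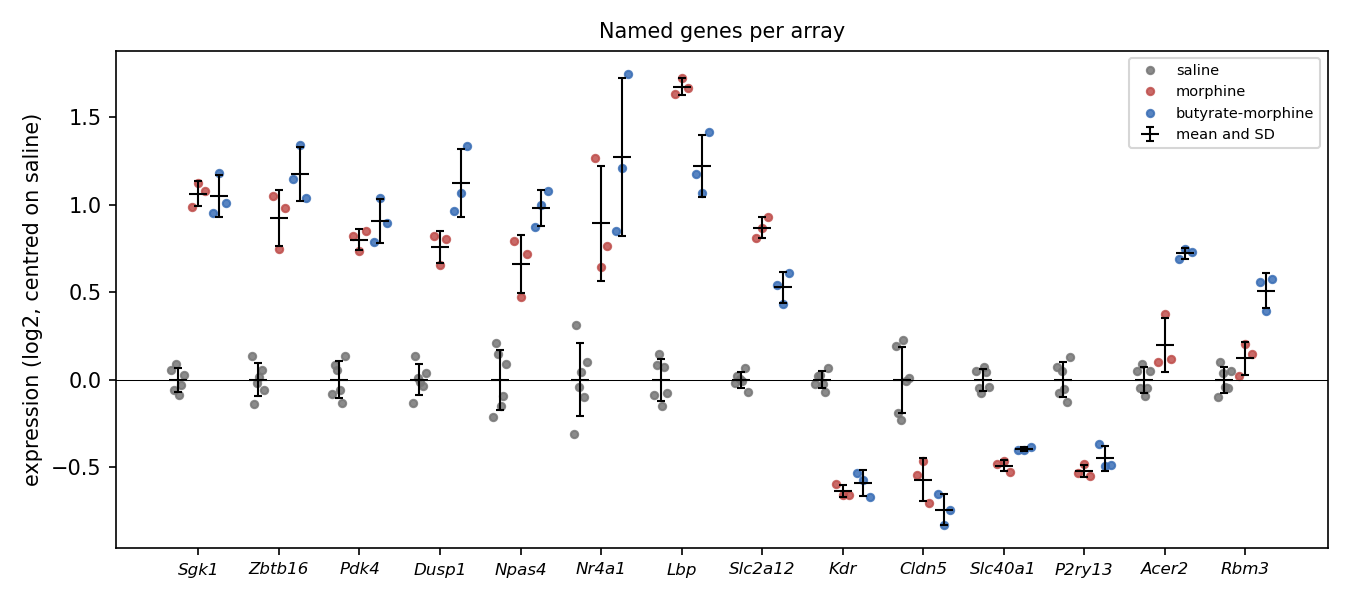
Expression of 14 named genes per array (y axis, log2 centred on saline; x axis, gene), with a point per array, the group mean as a dash and the SD as bars. Sgk1 lies near 1.06 in morphine and 1.05 in butyrate-morphine arrays, while Acer2 lies at 0.20 and 0.72.

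Both responses were then set side by side. Of the probe sets called in each comparison, 148 were higher in both and 62 lower in both. Both comparisons use the same saline arrays, and the overlap that this alone would give was not computed. Opposite calls numbered 0. Ttr, Kcnj13, Lbp, Polr3e, Sgk1, Kl, Zbtb16 and Nr4a1 were among the leading risers of both, and Kdr, Cldn5, Rasgef1b, P2ry13 and Slc40a1 among the leading falls of both. Across probe sets, which are not independent replicates, the 2 sets of log2 differences had a Pearson r of 0.677, against 0.334 for simulated unchanged groups sharing the same controls. Their covariance was 0.00725 against 0.00112, a difference of 0.00613. The simulated arrays were not centred on saline pairs as the deposited values are. Which pairs form each baseline is unknown, and the values for unchanged groups depend on it. Neither simulated value is therefore a firm reference. With the saline arrays split 3 and 3, r averaged 0.534 over 20 splits, but centring makes the opposing parts mirror images, so this split does not remove the shared controls.

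**Figure D3:**
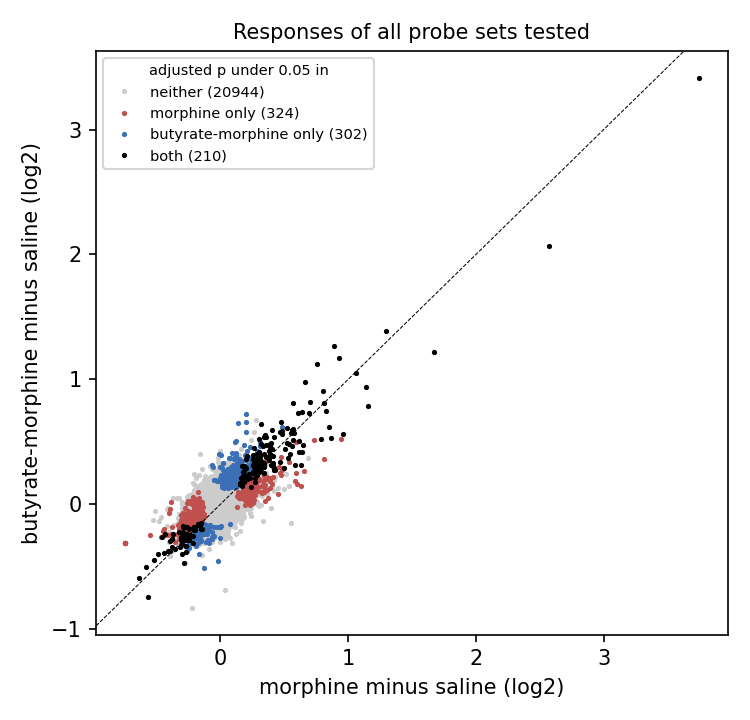
Difference from saline in morphine arrays (x axis, log2) and butyrate-morphine arrays (y axis, log2) for each probe set, coloured by where adjusted p was under 0.05, with the line of equality dashed. The 210 probe sets called in both lie in the upper right and lower left.

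The third comparison, butyrate-morphine against morphine, asks what butyrate during induction changed. No group received butyrate without morphine. An effect of butyrate itself thus cannot be told apart from a changed response to morphine. None of the 21780 probe sets passed with limma, and the smallest adjusted p was 0.101. An unadjusted p under 0.05 was seen for 1898, where the nominal rate gives 1089. In simulated arrays with independent genes, 5.7% of unchanged probe sets had such a p. This count was not taken in other splits of the arrays, so the excess is not a number of real differences. Acer2, an alkaline ceramidase, had the lowest p: it was at 0.72 ± 0.03 with butyrate and 0.20 ± 0.16 without (difference 0.52, SE 0.07). Slc2a12 was at 0.53 with butyrate and 0.87 without (adjusted p = 0.173), and Mrap2, a melanocortin receptor accessory protein, at 0.08 and 0.45. Rbm3, a cold-inducible RNA-binding protein, was at 0.51 with butyrate and 0.12 without.

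The other 6 of the 10 lowest p-values belonged to Mfsd13a (difference 0.27), the cyclophilin Ppie (-0.24), the Jumonji-domain gene Jmjd1c (0.24), Smyd5 (0.25), Efhd2 (0.28) and Acap3 (0.26). In each of the 10, all arrays of one group lay above all arrays of the other. Chance gives this for 10% of unselected genes with 3 against 3. Picking the lowest p-values favours such separation, so it adds no support. Leaving out morphine array 1 gave 27 calls and leaving out morphine array 3 gave 12. Leaving out morphine array 2 or butyrate-morphine array 1 gave 1 each, limma with array weights gave 1, and testing all rows gave 2. The median half-width of the 95% interval of this difference was 0.127, without adjustment over probe sets. Passing after that adjustment takes a larger difference: Acer2, at 0.52, did not pass with limma (adjusted p = 0.101). The absence of calls therefore does not exclude differences well above 0.127.

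Several lists leaned one way between the morphine groups, with no single member passing over all genes on all 12 arrays. Without morphine array 1, 1 immediate early gene passed, and without morphine array 3, 1 choroid plexus marker. All 12 dopamine signalling genes were higher with butyrate (median 0.0936), including Drd1 (0.18), Drd2 (0.11) and the signalling inhibitor Ppp1r1b, or DARPP-32 (0.20). Camera gave adjusted p = 9.15e-05, and adjusted p = 0.235 with an estimated correlation. Of 26 immediate early genes, 24 were higher with butyrate (median 0.111), with Btg2 at 0.39 and Dusp1 at 0.36 (camera adjusted p = 0.000795, and adjusted p = 0.361 with an estimated correlation). All 9 choroid plexus markers were lower with butyrate (median -0.264, camera adjusted p = 4.77e-09, and adjusted p = 0.189 with an estimated correlation). Thalamic and septal markers were lower too, with a median of -0.182. Of 6 cortical excitatory neuron markers, 5 were higher with butyrate (median 0.275, camera adjusted p = 0.0945). Among the morphine arrays, the means of the cortical and of the immediate early list were both highest in array 1 and lowest in array 2. The dopamine list mean was -0.092, -0.121 and -0.153 in morphine arrays 1 to 3, where the thalamic and septal mean was 0.09, 0.54 and 0.65. In butyrate-morphine arrays 1 to 3 these means were -0.045, -0.003 and -0.019, and 0.489, -0.07 and 0.244. Whether the dissected samples held unequal shares of striatum was not tested. Adjusted over the list alone, 1 dopamine signalling gene and 2 immediate early genes were higher and 4 choroid plexus markers lower. Camera called 10 lists in this comparison, of which 0 were called with an estimated correlation, and fry called 1, the direct-pathway markers. Camera called 6 without morphine array 3 and 6 without butyrate-morphine array 3.

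The size of the shared response was compared between the groups in 972 probe sets called by the mean of both morphine groups against saline, 590 higher and 382 lower. This number was 555, 638 and 595 without saline arrays 1, 2 and 4, 1482 without morphine array 1 and 630 without morphine array 3. The response was larger with butyrate in 490 of them (50.4%), with a median signed difference of 0.00059 (fry p = 0.868, two-sided exact permutation p = 1 over the 6 arrays, smallest possible 0.1). Among rising probe sets 348 of 590 responded more with butyrate (median 0.0205, fry p = 0.0843, exact permutation p = 0.3). Among falling ones 142 of 382 did (median -0.023, fry p = 0.137, exact permutation p = 0.4). Over all probe sets butyrate-morphine minus morphine had a median of 0.0111, and such an offset enlarges rises and shrinks falls. The median signed difference was -0.0522 without morphine array 1, where fry called a smaller response with butyrate. With unequal numbers of arrays, the choice of probe sets is no longer independent of this difference. It favours a larger response in the group with fewer arrays, here morphine. A smaller response with butyrate therefore cannot be read from this fit. Other causes of the shift were not tested.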

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

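The permutation of the choroid plexus list, the test for unequal change among endothelial genes and the clock score were chosen only after the result was seen. The lists below were picked out because camera found a difference between the butyrate-morphine and morphine arrays, and none of the 10 was called with an estimated correlation.

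All 9 choroid plexus markers were lower with butyrate than without (median -0.264) and higher than saline in both groups. Choroid plexus tissue in the dissected samples predicts higher levels of further genes of that tissue, and the median over 12 of these was 0.169 in the mean of both morphine groups, with 6 called (among them Slc13a4 at 0.44 and Aqp1 at 0.29), though 5 were called in morphine arrays (median 0.19) and only 1 in butyrate-morphine arrays (median 0.166, 3 of 12 lower). Dissection that varied from array to array without regard to group is argued against by the levels: the list mean was 0.91 to 1.46 in the 6 treated arrays and -0.11 to 0.11 in saline, though centring narrows the saline arrays. The exact permutation p of 0.00216, the smallest that 924 splits can give, only restates this separation, since the test was picked after it and saline arrays are mirror images. Dissection that differed between the groups, which is consistent with the further genes, stays open, as does a change of expression within choroid plexus cells, which was not tested.

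Of 9 endothelial markers, 8 were higher with butyrate than without (median 0.102), as were 14 of 15 further endothelial genes (median 0.0922, fry adjusted p = 0.00322), with 0 called, and the markers' median was below saline in both groups. A smaller share of vessel cells as the only change predicts no rises. In the mean of both groups, 3 of 15 further endothelial genes were called higher and 2 lower, and the higher ones argue against it. Of 24 endothelial genes, 10 had a 95% interval that left out their common median of -0.0714, where chance gives 1.2 if all change alike. That count does not decide, since genes also expressed in other cells fall by less. The 24 also include the markers that prompted the test. The glucose transporter Slc2a1 rose by 0.52 in the mean of both groups and the lipid transporter Mfsd2a by 0.43, while Eng fell by 0.30. A smaller share alongside other changes cannot be told apart from regulation of single endothelial genes, since the median of the further genes in the mean of both groups was -0.0643, between the values set for either outcome: it was -0.0938 for morphine, with 11 of 15 lower, and -0.0107 for butyrate-morphine, above the value set against a smaller share but over genes that went both ways (3 called higher, 1 lower). A response of endothelial cells to the treatments may account for genes that moved apart and was not tested.

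Of 15 circadian clock genes, 12 were higher with butyrate than without and 0 were called (median 0.123), with Arntl at -0.11 and Cry1 at -0.23. Genes that peak with Dbp minus genes that peak with Arntl gave a score 0.527 higher in butyrate-morphine than in saline arrays and 0.196 higher in morphine arrays. The exact permutation p of 0.0119 for butyrate-morphine, the smallest that 84 splits can give, only restates what prompted the test, since the score includes genes already seen to move and saline arrays are mirror images. Tissue taken at another time of day thus cannot be told apart from an effect of butyrate or of glucocorticoid signalling on clock genes, which was not tested, and the hour is not given in the sources used here.

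In the other lists 0 genes were called between the morphine groups. The median difference, with butyrate minus without, was 0.111 for immediate early genes (24 of 26 higher) and 0.0764 for glucocorticoid-responsive genes (21 of 26 higher). It was 0.0936 for dopamine signalling genes (12 of 12 higher) and 0.145 for direct-pathway neuron markers (7 of 8 higher), a list that fry called (adjusted p = 0.0414). It was -0.0653 for heat shock genes (1 of 12 higher) and -0.182 for thalamic and septal neuron markers (1 of 8 higher). For interferon-responsive genes it was -0.0458, with 4 of 12 higher and fry adjusted p = 0.417.

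Rows of the table without a single gene name, 7035 in all, were outside the comparisons of the report. Of these, 66 passed in morphine against saline, 63 in butyrate-morphine against saline and 2 in butyrate-morphine against morphine.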

How the results depend on the processing

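The added alternatives, against the baseline at 0, with mirror pairs counted once, with 1 value per gene and with stored values of 8 or more, were chosen only after the result was seen. Among alternatives that gave a correlation of both responses, it was lowest without morphine array 3, at 0.5269. A positive value can follow from the shared saline arrays alone, with 0.334 in simulated unchanged groups on all arrays. Those simulated arrays were not centred on saline pairs, so 0.334 is not a firm reference. Of 110 results for single genes, 46 kept direction and side of the threshold in every alternative. Over 2563 alternative values 427 lost a call, 6 gained one and 0 reversed. The planned brightness filters and the brightest probe set per gene were not run, since centred values keep only a coarse class of brightness, read from rounding, and no background level. Except where stated, the cause was not tested.

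Counts below are for morphine, butyrate-morphine and the mean of both, each against saline, in that order where 3 are given. Quantile normalization gave 69, 95 and 177, but on centred values it evens out the unequal spread of saline and other arrays. The eBayes fit with trend and robust gave 222, 218 and 531. Its trend ran over the mean of centred values, which follows the response and not brightness. Fewer saline arrays gave fewer calls: 92, 95 and 148 with arrays 1 to 3, and 93, 102 and 132 with arrays 4 to 6. Both subsets split the mirror pair of arrays 3 and 4, so they do not show the data without the other pools. A minimum of 1.2-fold gave 268, 261 and 242, and an adjusted p threshold of 0.10 gave 1015, 1108 and 1751, both by construction. Array weights gave 978 for butyrate-morphine, 1582 for the mean, 1 for butyrate-morphine against morphine and a boost of -0.009696. With only the groups compared, butyrate-morphine gave 1134. Testing all rows gave 2 for butyrate-morphine against morphine. Against the baseline at 0, morphine gave 290 (259 shared with the 534) and the mean gave 2128. Mirror pairs counted once gave 310, 314 and 1641. Both of these fits treat the morphine and butyrate-morphine arrays as independent. Saline baselines shared between them would make the counts for the mean too high. Stored values of 8 or more gave 208 (65 higher, 143 lower), 178 and 332 (155 higher, 177 lower), with fewer probe sets tested, and a boost of -0.001098.

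The replicate number as a block gave 49, 38 and 72 calls and a boost of -0.00897. Replicate numbers above those of the morphine arrays occur only in saline. As a block, each of these numbers holds 1 array, which then adds nothing to the comparisons. The block fit thus rests on fewer saline arrays and fewer residual degrees of freedom. Its lower counts therefore do not test pairing. Morphine and butyrate-morphine arrays with the same number were not more alike: their residuals had r of -0.105, -0.267 and -0.226 over probe sets. With different numbers r ran from -0.138 to 0.306. It was 0.231 for morphine array 1 with butyrate-morphine array 2, 0.306 for 2 with 3 and 0.156 for 3 with 1. Saline arrays with the same number gave r of -0.195 to 0.202. Equal numbers thus do not pair the 2 morphine groups, and pairing under another numbering stays open.

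Leaving out each array in turn gave 219 to 1092 calls for morphine, 206 to 807 for butyrate-morphine, 0 to 27 for butyrate-morphine against morphine and 555 to 1482 for the mean. The boost ranged from -0.0522 to 0.03203, and was below 0 without saline array 1 (-0.003817), saline array 4 (-0.001309), morphine array 1 or morphine array 2 (-0.01526). Without an array of 1 morphine group, the choice of probe sets is tied to the tested difference. It then favours a larger response in the group with fewer arrays. Gene lists called numbered 9 to 12 for morphine, 9 to 13 for butyrate-morphine and 6 to 12 between them. With the estimated correlation, camera called 3, 2 and 0 lists in these comparisons, and fry called 1 between the morphine groups.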

Other observations

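The lists of endoplasmic reticulum, cold-inducible and hypothalamic genes were chosen only after the result was seen; the splits of the arrays were planned.

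Endoplasmic reticulum chaperone and stress genes leaned lower in butyrate-morphine arrays. Of 20 measured, 16 were below saline (median -0.108) and 2 fell, the stress transcription factor Ddit3 (by 0.31) and Sdf2l1 (by 0.51), with 1 rise and 7 falls when adjusted over the list alone. Fry gave adjusted p = 0.0227 by limma, and camera with an estimated correlation did not call the list. In morphine arrays the median was -0.0117, with Herpud1 higher (0.25) and Xbp1 lower (-0.24). The difference between the morphine groups had fry adjusted p = 0.106 by limma.

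The cold-inducible RNA-binding genes Rbm3 and Cirbp, as means of their probe sets, were at 0.47 and 0.24 in butyrate-morphine arrays, and Rbm3 passed (adjusted p = 0.000822). In morphine arrays they were at 0.11 and 0.06, and neither passed. The pair was picked because Rbm3 had among the lowest p-values between the morphine groups. Of 9 hypothalamic neuron genes, 0 rose and Sim1 fell by 0.17 in butyrate-morphine arrays. Oxt was at 0.55 in morphine arrays (adjusted p = 0.0621), with an SD of 0.46.

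Other splits of the same arrays were counted, but centring makes saline arrays vary less (SD over probe sets 0.052 to 0.0845) than the others (0.112 to 0.151). This favours the real split, so the counts against saline do not by themselves exclude chance. For morphine against saline, 1 of 84 splits gave as many as the real 534 calls and the highest other gave 13. For butyrate-morphine against saline, 1 of 84 gave as many as 512 and the highest other gave 14. For the mean of both, 1 of 100 gave as many as 972 and the highest other gave 1. For butyrate-morphine against morphine the 10 splits are too few for a share under 0.05: the real count was 0, which all 10 reach, and the highest other was 4.

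For the number of gene lists called by camera, chance could not be excluded. In morphine against saline 11 of 84 splits gave as many as the real 10, and the highest other gave 12. In butyrate-morphine against saline 11 of 84 gave as many as 9, and the highest other gave 12. Between the morphine groups the 10 splits are too few, with 10 lists in the real split, reached by 1 of them, and 7 in the highest other.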
